A study of Mus musculus with 12 samples.

How the data were processed

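The series mapped 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine that Tet enzymes make, in mouse cerebellar granule cells. Genomic DNA came from purified granule cells of postnatal day 7 (P7) and from sorted GFP-positive granule cells that had been derived from embryonic stem (ES) cells and kept in culture for 15 days (D15), per the labels. The D15 cells had either been left untreated or been given vitamin C, a known cofactor of Tet enzymes. Fragments of about 200 bp carrying 5hmC were captured with hMe-Seal, in which a glucose bearing a chemical handle is put onto 5hmC and pulled down with biotin, and were sequenced beside input DNA, per the labels. Each of the 3 groups had 2 capture and 2 input libraries, 12 in all.

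The submitters' processing notes name Bowtie2 and the mouse build mm10, with no version. The authors deposited 3 lists of summits, 1 per group, and the labels tie each list to all 4 libraries of its group, which was taken to mean that the replicates had been pooled. The peak names in the deposited lists are those that MACS writes; its version and threshold are not given in the sources used here. Each row of a list is the 1 bp position of an enrichment summit with a score column. That column was read as the signal at the summit, the height of stacked fragments that the authors' peak caller gives, because its values were whole in 100% of rows and no file header names it. The heights were not scaled between lists, so they were used only to rank summits within a list. The number of sequenced reads behind each list is unknown, and since a deeper library yields more summits, numbers of summits were compared only after scaling or thinning. With 1 list per group there was no replicate check, and no p-value was computed for any comparison.

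Positions were read as 1-based coordinates. Genes were taken from a RefSeq table of assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes and 49943 genes of any type on placed chromosomes. The table gives spans without strand or exons. Shares in promoters, exons and introns, which had been planned, were therefore replaced by shares within 1 kb of either end of a gene, and a planned 5 kb upstream extension was replaced by 5 kb on either side. A summit inside overlapping genes was counted in each of them.

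A summit was called shared when a summit of the other list lay within 200 bp. Chance was the mean of 100 circular shifts of the other list along each chromosome and, as a stricter background added later, of 20 shifts by 5 to 20 kb. The vitamin C list was also thinned at random to the length of the untreated list in 100 draws. Shares carry exact (Clopper-Pearson) 95% intervals. For each protein-coding gene, the summits between its annotated ends were divided by the number of summits in the list, and the ratio of these shares between lists was given an exact 95% interval from the split of the gene's summits. A gene was called higher or lower when it had at least 20 summits in the pair of lists, a ratio of at least 1.5 or its inverse, and an interval that excluded 1. All these intervals cover counting error only, because summits are neither molecules nor replicates. The number of calls that arises with no difference was taken from 100 random splits of each gene's summits in proportion to list length and, in an alternative added later, from 100 splits of only those summits that had no partner in the other list, with shared summits kept. Where a gene had 0 summits in a list, its ratio was computed against a floor of 3 summits, and the exact lower limit is given beside it. When genes with known ratios were simulated for the comparison of vitamin C with untreated cells, over 3180 genes, 68.0% of 50 genes raised 2-fold and 100% of 50 genes raised 4-fold were called, against 42.0% of 50 genes lowered to 0.5 and 3.49% of 3007 unchanged genes. For P7 against untreated cells, over 3148 genes, the call rates for genes raised 2-fold and lowered to 0.5 were 78.0% and 46.0%. Genes lowered to 0.25 were called in 72.0% of cases for vitamin C against untreated cells, 48.0% for P7 against untreated cells and 64.0% for P7 against vitamin C cells. Only the counts of the first-named list were changed in these simulations. Lowered genes therefore lost summits, and those under the minimum of 20 counted as missed. Because the gap between raised and lowered genes follows from this setting, it cannot tell whether lower calls are missed more often in the data.

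The 20 gene lists were granule cell progenitor, granule neuron maturation, axon guidance, voltage-gated ion channels, glutamate and GABA receptors, synaptic adhesion and scaffold, migration and polarity, Tet and DNA methylation, chromatin remodeling, cell cycle, pluripotency, Purkinje cell, astrocyte and Bergmann glia, oligodendrocyte lineage, cerebellar inhibitory interneuron, microglia and endothelium, mesoderm and endoderm, Hox, anterior brain patterning, and housekeeping. All 471 of their symbols were in the gene table. A list's median log2 ratio, with 0.5 summits added to each count, was taken over members with at least 10 summits in the pair, where at least 5 members qualified. It was set against 10000 random lists of the same size matched on summit count and is given as a percentile among them, a description of these lists and not a test across replicates. A scaling of a whole list moves a gene list and its random lists alike, so it leaves the percentile as it is. Named genes were chosen by a rule: in each pair, the 10 protein-coding genes with the highest lower bound and the 10 with the lowest upper bound of the interval; in each gene list, the members with the highest and lowest ratio among those with at least 20 summits in the pair, and the member with the most summits; and Tet1, Tet2 and Tet3. One result under this rule is not reported here. Groups, gene lists, this rule, the comparisons and the alternatives listed next, unless named as added, were fixed before the data were examined. The alternatives were other sharing distances, the tallest 50% of each list, an equal number of the tallest summits, merged neighbouring summits, no sex chromosomes, other scalings, other minimum counts and matching on gene length. Flanks of 5 kb, gene counts without sex chromosomes, matching on summit density, sums over all members of a list, tall untreated summits against the whole vitamin C list, shifts of 5 to 20 kb, windows ranked by gene content, the tallest 50% applied to chromosomes and windows, and the splits over 3 lists or with shared summits kept were added after seeing the data. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.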

Results

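Captured 5hmC was compared between D15 granule cells made from ES cells without treatment, D15 cells made with vitamin C, and granule cells of the P7 cerebellum, with 2 capture libraries in each of the 3 groups. The series' title places the work in the study of Tet1, Tet3 and chromatin remodeling during the formation of cerebellar circuits. The untreated list held 190288 summits with a median height of 24.0 stacked fragments, the vitamin C list 250008 with a median of 36.0, and the P7 list 257655 with a median of 45.0. Typical spacing between neighbouring summits was 4819, 3724 and 3930 bp in that order. Read depth is unknown and each group has 1 list, so no difference below has a replicate check. Every interval covers counting error only, except the range over random draws given for autosomal windows matched to X.

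In all 3 groups 5hmC summits lay inside genes more often than chance placed them. Gene bodies held 65.0% of untreated, 66.0% of vitamin C and 63.7% of P7 summits, against 49.2%, 49.7% and 49.6% after circular shifts, which is 1.32, 1.33 and 1.28 times chance. The zones within 1 kb of either gene end held 9.04%, 8.98% and 9.37%, against 6.43%, 6.39% and 6.40% by chance. The 95% interval of the P7 gene-body share ran from 63.5% to 63.8% and lay below that of the untreated list, 64.8% to 65.2%. With the tallest 50% of each list this order was lost, with 65.8% of P7 summits (65.6% to 66.1%) and 65.7% of untreated summits (65.4% to 66.0%) in gene bodies.

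The Tet genes themselves carried summits in every list. Tet3, on chromosome 6 from 83362373 to 83457208, held 31 summits in untreated, 28 in vitamin C and 26 in P7 cells. Tet1, on chromosome 10 from 62804570 to 62887469, held 13, 12 and 17, and Tet2, on chromosome 3 from 133463677 to 133545136, held 11, 15 and 6. No ratio between groups had an interval that excluded 1 for any of these genes; the lowest was that of Tet2 between P7 and vitamin C cells, 0.388 with an interval of 0.123 to 1.06.

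The comparison of vitamin C with untreated D15 cells asks where 5hmC differed when vitamin C, a known cofactor of Tet enzymes, was given in culture. Ranked by the lower bound of the interval, Zeb1, a zinc-finger repressor known from epithelial-mesenchymal transition, headed the genes with a larger share under vitamin C. It lies on chromosome 18 from 5591327 to 5775468 and had 40 summits against 10, a ratio of 3.04 after scaling to list length (95% interval 1.496 to 6.83). Spag9, a scaffold of JNK signalling, had a ratio of 2.92, and Evl, an actin regulator of the Ena/VASP family, had 2.59. Slc4a4, a sodium bicarbonate cotransporter of astrocytes, had 62 summits against 26 and a ratio of 1.82 (1.13 to 2.99). At the other end stood Dmd, the dystrophin gene on chromosome X from 82814664 to 85205050, with 5 summits against 16 and a ratio of 0.238 (0.0681 to 0.680). That interval includes 0.560, the ratio of chromosome X as a whole, so Dmd cannot be told apart from the rest of X. Chd7, a chromatin remodeler on chromosome 4 from 8690402 to 8868449, had 38 against 59 and a ratio of 0.490 (0.317 to 0.749).

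The other genes at the high end were Zfp236, Ppm1e, Plcl2, Cped1, Klf12 and Srbd1, with ratios from 1.46 in Klf12 to 3.62 in Zfp236. Those at the low end were Gse1, Mgat4c, Faf1, Kcnip4, Lrp1b, Kif26a, Ephb2 and Galnt2, from 0.269 in Mgat4c to 0.530 in Ephb2. Kcnip4, which encodes a partner of A-type potassium channels, had 16 summits against 31, and Ephb2, an ephrin receptor, had 48 against 69. Kcnip4 had only 26 P7 summits over 1135620 bp and Mgat4c 11 over 710365 bp. Their intervals, 0.201 to 0.741 and 0.0867 to 0.714, include 0.616, the ratio of autosomal 1 Mb windows with 13 to 27 P7 summits (below). These genes therefore cannot be told apart from the trend of sparse regions. Of 3134 measured genes, 20 were called higher and 63 lower. Random splits of the same summits gave 48.0 higher and 50.9 lower genes on average and at most 66 and 67, but they treat all summits as independent, whereas 49.6% of untreated summits have a vitamin C partner. When shared summits were kept in both lists and only the others were split, which was added after seeing the data, the splits gave 8.07 and 7.06 on average and at most 15 and 16. Whether the 20 and 63 calls exceed chance therefore depends on how shared summits are treated. With unscaled counts the calls were 282 higher and 6 lower and the median log2 ratio of all genes moved from 0.01 to 0.40, and scaled to summits outside genes they were 34 and 55. With the tallest 50% of each list the intervals of 12 of these 20 genes reached 1, among them Spag9 (ratio 1.14), Slc4a4 (1.69), Dmd (0.761) and Chd7 (0.658).

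Glutamate and GABA receptor genes and axon guidance genes had low vitamin C shares. Summed over all members, which was added after seeing the data, their ratios were 0.866 (0.786 to 0.954) and 0.868 (0.814 to 0.925). Low summed shares were not limited to these lists. The ratios of anterior brain patterning genes, 0.788, and of synaptic adhesion and scaffold genes, 0.924, also had intervals below 1. That of cell cycle genes, 1.67, had an interval above 1. Among 24 measured glutamate and GABA receptor genes the median log2 ratio was -0.29, at percentile 0.01 of matched random lists, and 2 members had intervals below 1 and 0 above. These were Grm5, with a ratio of 0.217 (0.0521 to 0.692), and Gria3, with 0.272 (0.0766 to 0.799), named after their values were seen. Gria3 lies on chromosome X and its interval includes 0.560, the ratio of X as a whole, so it cannot be told apart from the rest of X. Without sex chromosomes the receptor list lay at percentile 0.03. Among members with at least 20 summits in the pair, the minimum for the lowest and highest members named in this report, Gabrg3 was lowest, with a ratio of 0.507 (0.204 to 1.21), and Grik5 highest, at 1.61 (0.693 to 4.03). Axon guidance genes had a median of -0.18 over 42 members, at percentile 0.11, and 8 members had intervals below 1 and 0 above. The lowest of them was Sema3d, a secreted semaphorin, at 0.361 (0.144 to 0.836). Voltage-gated ion channels had a median of -0.15 over 33 members, at percentile 1.46, with 1 interval on either side of 1 and a summed ratio of 0.982 (0.905 to 1.06); Cacna1b was highest at 3.04 (0.982 to 12.5) and Kcnip4 lowest at 0.393 (0.201 to 0.741).

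None of the remaining lists lay in the outermost 2.5% at either end. Synaptic adhesion and scaffold genes had a median of -0.12 (percentile 5.60), granule cell progenitor genes -0.25 (3.71), granule neuron maturation genes -0.01 (46.8), migration and polarity genes -0.01 (49.0), Tet and DNA methylation genes -0.14 (20.4) and chromatin remodeling genes 0.14 (89.0). Markers of other cells were placed at percentile 6.02 for Purkinje cells, 50.4 for astrocytes and Bergmann glia, 7.84 for the oligodendrocyte lineage, 38.7 for inhibitory interneurons and 4.43 for anterior brain patterning. With the tallest 50% of each list and with an equal number of the tallest summits, synaptic genes lay at percentile 0 and 0 and Purkinje markers at 0.77 and 1.25, inside the outermost 2.5%, while progenitor genes moved to 62.0 and 72.8. Lowering the minimum to 1 summit put Tet and DNA methylation genes at percentile 1.535, anterior patterning genes at 0.025 and chromatin remodeling genes at 98.0. Flanks of 5 kb, added after seeing the data, put chromatin remodeling genes at 98.3 and anterior patterning genes at 0.58. Random lists matched on P7 summit density, also added, put progenitor genes at percentile 1.52, receptors at percentile 1.18 and axon guidance at 0.42, and with the tallest 50% of each list the receptors moved to 9.10. Ion channels left the outermost 2.5% when random lists were matched on gene length (percentile 4.12), with an equal number of the tallest summits (2.78), with flanks of 5 kb (4.13) and when matched on P7 summit density (3.02).

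**Figure D1:**
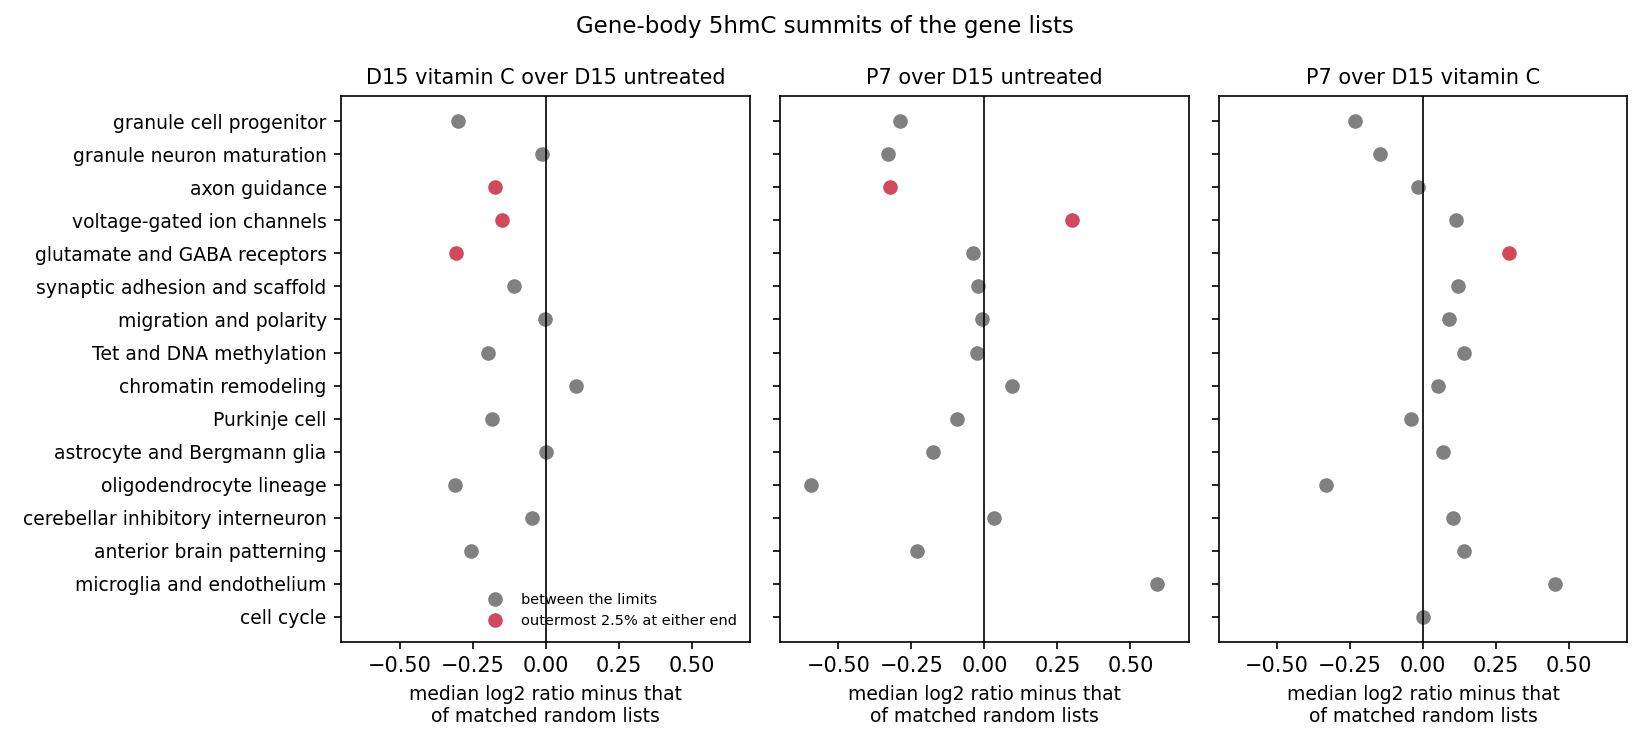
Median log2 ratio of gene-body 5hmC summits for each gene list minus the median of matched random lists (horizontal axis, log2), with 1 panel per pair of groups and 1 point per list with at least 5 measured members; red points lie in the outermost 2.5% at either end of 10000 random lists. Glutamate and GABA receptors sit low for vitamin C over untreated (percentile 0.01) and high for P7 over vitamin C (percentile 99.9). Both pairs use the same vitamin C list, so these positions are not independent.

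Regions poor in 5hmC held relatively fewer vitamin C summits. In autosomal windows of 1 Mb ranked by P7 summits, the sparsest of 10 classes had 805 vitamin C and 1404 untreated summits, a ratio of list shares of 0.436 (0.400 to 0.476). The ratio was 0.616 in the next class and 0.787 in the one after, lay between 1.05 and 1.06 in classes 7 to 9, and was 1.01 in the densest. With windows ranked instead by the share of their bases inside genes, which was added after seeing the data, the ratio was 0.659 (0.630 to 0.689) in the class with the smallest share and 0.880 in the next. Chromosome X held 927 vitamin C and 1259 untreated summits, a ratio of 0.560 (0.514 to 0.611), while single autosomes ranged from 0.959 to 1.04, and from 0.964 to 1.07 with the tallest 50% of each list. The lowest autosome, chromosome 8, was then the highest, with 1.07 (1.04 to 1.11) in place of 0.959 (0.936 to 0.983). Its P7 ratios fell further below 1, from 0.929 to 0.762 (0.737 to 0.788) against untreated and from 0.969 to 0.710 (0.688 to 0.732) against vitamin C cells. The tallest 50% kept 7068 of 14359 P7 summits on chromosome 8, against 6848 of 11410 untreated and 9659 of 14379 vitamin C summits. The fall thus came with many tall summits there in both D15 lists rather than with a loss of P7 summits, and its cause was not tested. Summits per Mb on X came to 9.58% of the autosomal density in untreated, 5.35% in vitamin C and 9.14% in P7 cells.

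**Figure D2:**
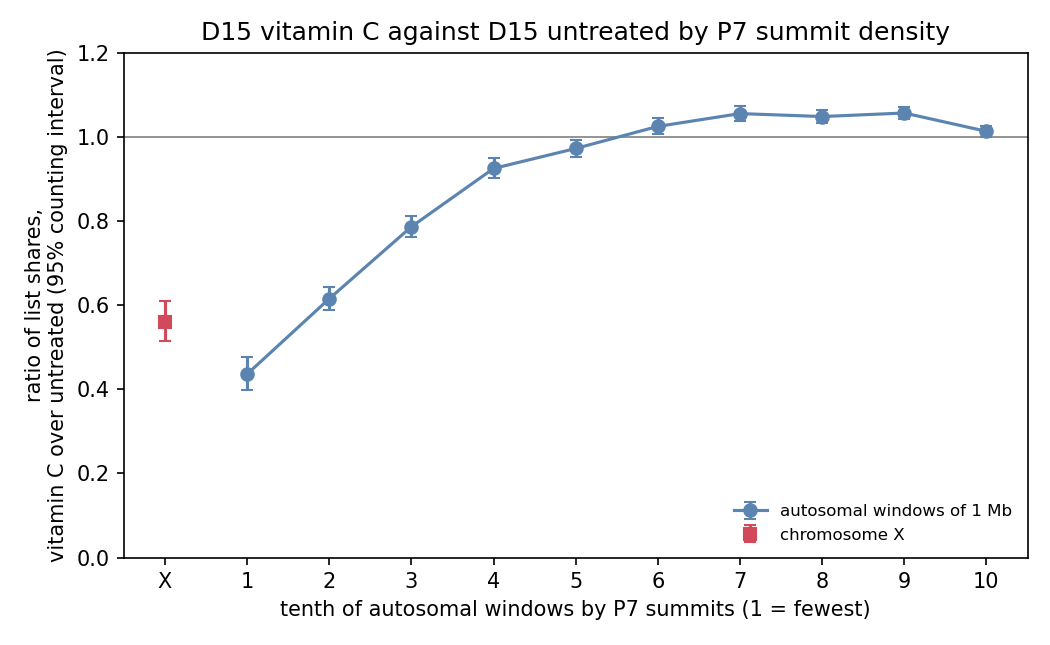
Ratio of list shares of 5hmC summits, vitamin C over untreated D15 cells (vertical axis, points with exact 95% counting intervals), for 10 classes of autosomal 1 Mb windows ordered by their number of P7 summits (circles, class 1 has the fewest) and for chromosome X (square). The ratio is 0.436 in the sparsest class, near 1 from class 5 on, and 0.560 on X.

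The comparison of P7 granule cells with untreated D15 cells asks how the 5hmC of cells made in culture differed from that of cells from the cerebellum. Fat2, a giant cadherin of granule cells on chromosome 11 from 55250609 to 55337505, had 22 summits in P7 cells and 0 in untreated cells, a share at least 4.05-fold higher by the lower limit of the exact 95% interval, and 5.42-fold higher against a floor of 3 untreated summits. Csmd1, on chromosome 8 from 15892538 to 17535385, had 82 against 11 and a ratio of 5.51 (2.92 to 11.5), and Cemip, on chromosome 7 from 83932857 to 84086693, had 35 against 2 and a ratio of 12.9 (3.32 to 111). Genes with small P7 shares included Ncam2, a neural adhesion molecule on chromosome 16 from 81200697 to 81624290, with 5 against 37 (ratio 0.0998, 0.0306 to 0.255). Slit2, a repulsive axon guidance ligand on chromosome 5 from 47981291 to 48307735, had 12 against 54 (0.164, 0.0799 to 0.311).

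Foxp2, a transcription factor that marks Purkinje cells, had 22 P7 summits against 71, a ratio of 0.229 (0.135 to 0.374), over chromosome 6 from 14901349 to 15441977. The other genes at the high end were L3mbtl4, Caln1, Cpne4, Epha6, Loxhd1, Cfap46 and Pde1c, with ratios from 3.32 in Pde1c to 7.75 in Cfap46, the latter on 2 untreated summits (1.90 to 68.2). The others at the low end were Faf1, Edil3, Mipol1, Chd7, Nalcn, Dpyd and Rsrc1, from 0.176 in Faf1 to 0.345 in Dpyd. Nalcn, a sodium leak channel, had 6 against 21. Of 3070 measured genes 134 were called higher and 212 lower in P7 cells, whereas random splits gave 49.8 and 48.4 on average and at most 71 and 66, and splits that kept shared summits in both lists gave at most 35 and 35. Without scaling the calls were 444 higher and 45 lower, and the median log2 ratio of all genes moved from -0.13 to 0.31.

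Axon guidance genes had small P7 shares as a group. Their median log2 ratio was -0.48 over 40 members, at percentile 0.03, with 12 intervals below 1 and 2 above; Slit2 was the lowest, Sema6d the highest at 1.53 (1.04 to 2.28), and Robo1, a Slit receptor, had the most summits, 142 in P7 against 178 in untreated cells. Voltage-gated ion channels lay the other way, with a median of 0.15 over 34 members at percentile 99.7 and 5 intervals above 1 against 2 below, though their summed ratio was 1.08 (0.995 to 1.16). Cacna1b, a presynaptic calcium channel gene, had 18 summits against 4 and a ratio of 3.32 (1.09 to 13.5), and Kcnc2, a fast potassium channel gene, had 16 against 25 and a ratio of 0.473 (0.236 to 0.921). With an equal number of the tallest summits the axon guidance percentile was 7.34 and that of the channels 89.5, and with random lists matched on vitamin C summit density, added after seeing the data, the channels lay at 87.3.

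None of the other lists lay in the outermost 2.5% at either end. Granule neuron maturation genes had a median of -0.44 over 10 members (percentile 3.65), with Fat2 at the top and Grm4 lowest at 0.597 (0.319 to 1.103), and progenitor genes -0.37 over 9 members (11.3), with Gli2 at 1.11 and Hhip at 0.625. The receptor list, at percentile 35.8, held Grm7, a presynaptic glutamate receptor with 27 against 4 summits (4.99, 1.74 to 19.6), and Grm5, a postsynaptic one with 6 against 14 (0.317, 0.0997 to 0.877). Synaptic genes lay at percentile 40.9, migration genes at 47.7, Tet and DNA methylation genes at 47.6 and chromatin remodeling genes at 71.7. Purkinje markers were placed at 24.5, astrocyte and Bergmann glia markers at 23.1, oligodendrocyte markers at 3.42, inhibitory interneuron markers at 54.8, microglia and endothelium markers at 95.5 and anterior patterning genes at 13.0. With the tallest 50% of each list and with an equal number of the tallest summits, maturation genes moved to percentile 68.0 and 88.5 and progenitor genes to 63.3 and 88.7, above the middle of their random lists. With the equal number, migration genes lay at 99.0 and Purkinje markers at 1.97, and with the added flanks of 5 kb astrocyte markers lay at 1.29 and oligodendrocyte markers at 1.18. With no minimum beyond 1 summit, progenitor genes went the other way, to percentile 0.09, interneuron markers lay at 1.21 and maturation genes at 19.96.

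**Figure D3:**
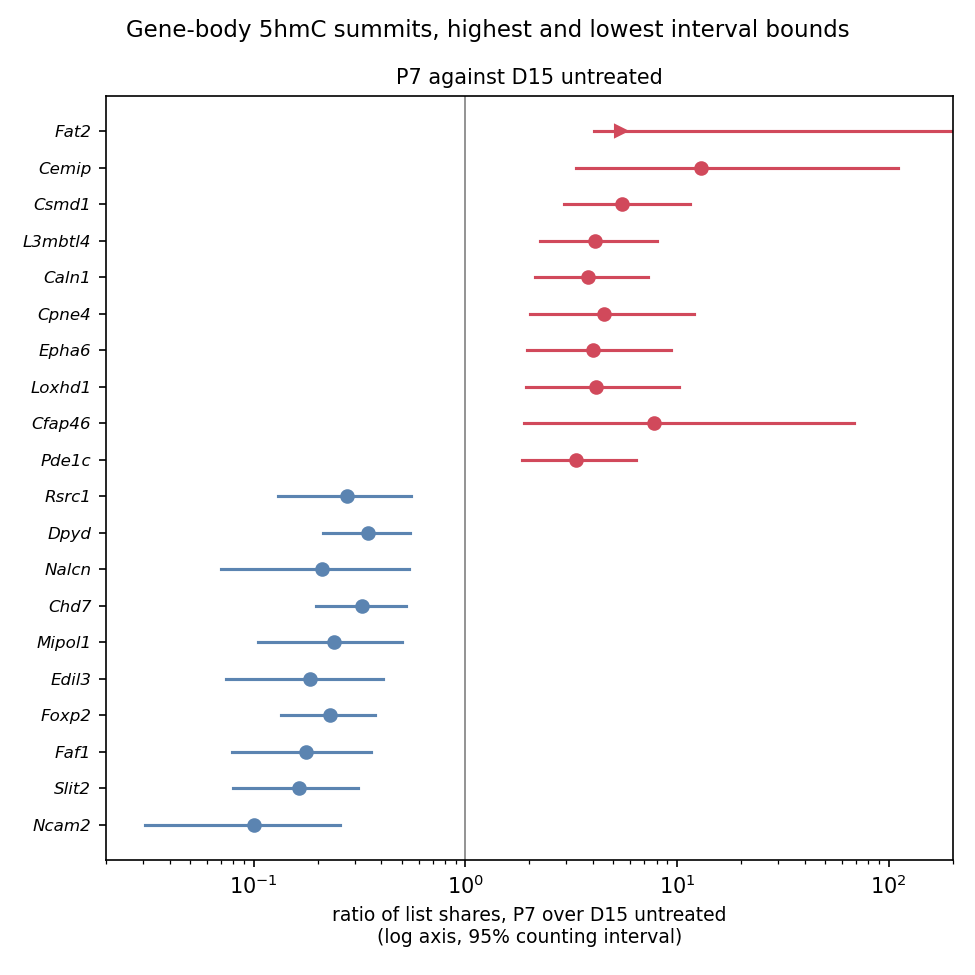
Ratio of list shares of gene-body 5hmC summits (horizontal log axis) in P7 over untreated D15 cells, for the 10 genes with the highest lower bound (red) and the 10 with the lowest upper bound (blue); lines are exact 95% counting intervals. The arrow for Fat2 marks its ratio of 5.42 against a floor of 3 untreated summits, and its interval starts at 4.05; Ncam2 is lowest, at 0.0998.

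The comparison of P7 with vitamin C D15 cells asks the same of the treated culture. Grm7, on chromosome 6 from 110645349 to 111567230, had 27 P7 summits against 2, a ratio of 13.1 (3.29 to 114). Epha6, an ephrin receptor on chromosome 16 from 59641433 to 60610911, had 49 against 6 (7.92, 3.39 to 22.6). Small P7 shares were again found in Ncam2, with 5 against 30 (0.162, 0.0490 to 0.421), in Foxp2, with 22 against 80 (0.267, 0.159 to 0.432), and in Slit2, with 12 against 46 (0.253, 0.122 to 0.486). With the tallest 50% of each list the intervals of Ncam2 (ratio 0.291), Eml5 (0.323) and Rasal2 (0.522) reached 1.

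The others at the high end were Nkain2, Csmd1, Cemip, L3mbtl4, Pde1c, Cpne4 and Car10, with ratios from 3.40 in Car10 to 12.6 in Nkain2, the latter on 2 vitamin C summits (3.16 to 110). Those at the low end were Mipol1, Hsd17b12, Qk, Fat3, Eml5, Rasal2 and Nckap5, from 0.202 in Hsd17b12 to 0.474 in Nckap5. Fat2 had 22 summits against 5 and a ratio of 4.27 (1.58 to 14.4). Of 3533 measured genes 105 were called higher and 163 lower in P7 cells, against 56.2 and 56.4 on average and at most 72 and 73 in random splits, and at most 24 and 24 in splits that kept shared summits. Scaled to summits outside genes the calls were 85 higher and 224 lower. Among the 3028 genes measured in both P7 comparisons, 66 were higher in P7 than in either D15 group and 85 were lower, where independent calls would give 4.4 and 9.4. Both comparisons use the same P7 list, and random splits of each gene's summits over the 3 lists, added after seeing the data, gave 7.50 and 7.25 such genes on average and at most 19 and 15; these splits do not keep the sites that the D15 lists share.

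Glutamate and GABA receptor genes had larger shares in P7 than in vitamin C cells, with a median log2 ratio of 0.19 over 27 members at percentile 99.9 and 3 intervals above 1 against 0 below. The percentile was 92.5 with the tallest 50% of each list, 95.8 with an equal number of the tallest summits and 79.8 with random lists matched on untreated summit density, which was added after seeing the data. Ion channels lay at 94.4, with 8 intervals above 1, and synaptic genes at 96.7, where Cntnap2 had 60 summits against 27 (2.16, 1.35 to 3.53). With the tallest 50% of each list and with an equal number of the tallest summits, ion channels lay at 99.5 and 99.9 and synaptic genes at 99.6 and 100, inside the outermost 2.5%. Axon guidance genes lay at 39.1, migration genes at 83.9, progenitor genes at 10.1, maturation genes at 14.4, Tet and DNA methylation genes at 75.8, chromatin remodeling genes at 67.7 and cell cycle genes at 49.8. Markers were placed at 39.7 for Purkinje cells, 62.8 for astrocytes, 12.7 for oligodendrocytes, 68.8 for interneurons, 96.2 for microglia and endothelium and 81.9 for anterior patterning.

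Single 5hmC sites of P7 cells were found more often in the vitamin C list than in the untreated list. Of the P7 summits, 33.1% (32.9% to 33.3%) had a vitamin C summit within 200 bp and 19.7% (19.6% to 19.9%) an untreated one, against 7.11% and 5.34% after shifts of 5 to 20 kb (added after seeing the data) and 4.20% and 3.18% after circular shifts. When the vitamin C list was thinned to 190288 summits it still held 25.2% of the P7 sites (SD over draws 0.0424), 1.28 times the untreated share. In the other direction 34.1% (34.0% to 34.3%) of vitamin C and 26.7% (26.5% to 26.9%) of untreated summits had a P7 summit. Either direction counts the same 85353 vitamin C and 50876 untreated matches. The thinned ratio of 1.28 therefore restates the ratio of these shares and is no separate support. The D15 lists were closest to each other, with 49.6% of untreated summits in the vitamin C list and 37.8% of vitamin C summits in the untreated list.

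Of the P7 summits, 13.9% were in both D15 lists, 19.2% in the vitamin C list alone, 5.84% in the untreated list alone and 61.0% in neither. Vitamin C summits without an untreated partner had a P7 summit in 31.2% of cases and those with a partner in 39.0%. For untreated summits the shares were 15.4% without a vitamin C partner and 38.3% with one. Taller P7 summits were shared more often: from the lowest to the highest of 5 height classes the share rose from 15.4% to 25.7% in the untreated list and from 26.4% to 42.4% in the vitamin C list. Height told apart shared vitamin C summits, from 15.7% to 62.1% in the untreated list, more than shared untreated ones, from 44.5% to 49.8% in the vitamin C list.

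**Figure D4:**
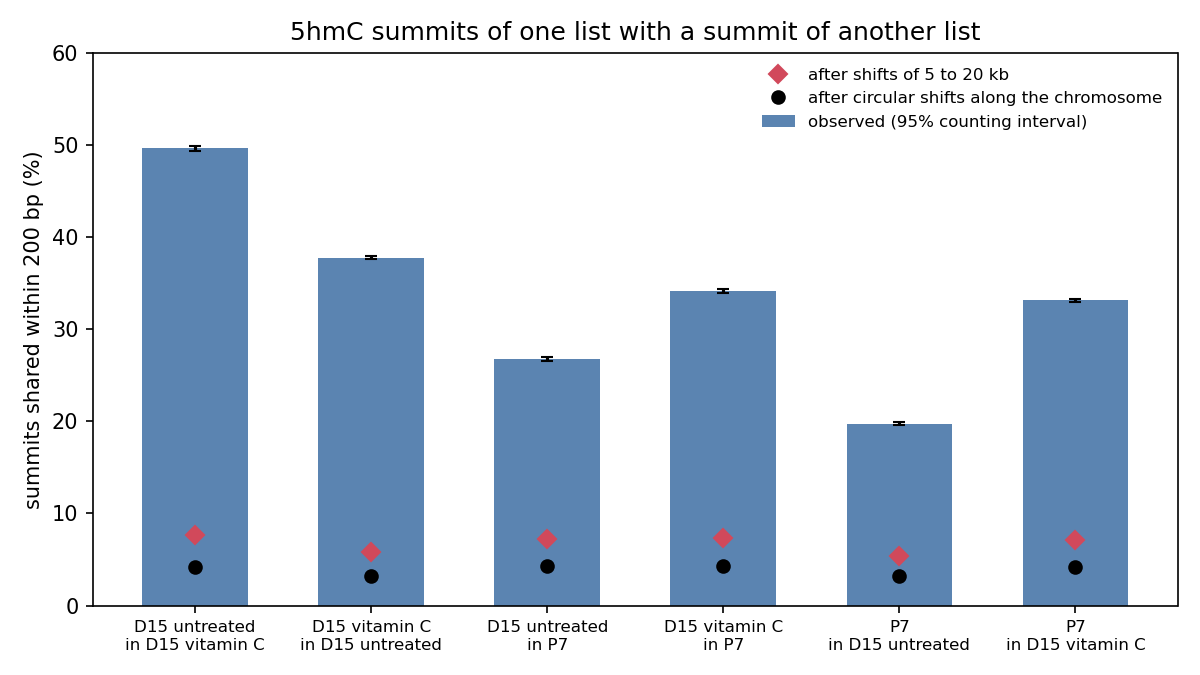
Share of 5hmC summits of the first list that have a summit of the second list within 200 bp (bars, percent, with exact 95% counting intervals), beside the share after shifts of 5 to 20 kb (diamonds) and after circular shifts (circles). P7 summits are found in the vitamin C list (33.1%) more often than in the untreated list (19.7%), and both lie above the shifted shares.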

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

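The flanks of 5 kb, the lists without sex chromosomes applied to genes, the shifts of 5 to 20 kb, the matching on summit density, the sums over list members, the tall untreated summits set against the whole vitamin C list, the windows ranked by gene content, the tallest 50% applied to chromosomes and windows, and the random splits over 3 lists or with shared summits kept were chosen after seeing the data; the rest were planned. No paired analysis was possible because each group has 1 list that joins its libraries, and for the same reason no library could be left out. Shares in promoters, exons and introns and the 5 kb upstream extension were not run, since the gene table has no strand or exons. None of the 60 ratios of the 10 genes at either end of each comparison crossed 1 unscaled or with the tallest 50%; other named genes were not rerun, and Tet1, with a P7 to untreated ratio of 0.966, had 17 against 13 summits before scaling. No gene list in the outermost 2.5% crossed the median of its random lists. Other values did turn, among them these: with the tallest 50% of each list the vitamin C to untreated ratio of chromosome 8 went from 0.959 (0.936 to 0.983) to 1.07 (1.04 to 1.11) and the gene-body shares of P7 and untreated summits changed order, with these and with an equal number of the tallest summits maturation genes (P7 against untreated cells) and progenitor genes (both comparisons with untreated cells) crossed the median of their random lists, and with unscaled counts more genes were higher than lower under vitamin C. Gene calls against untreated cells moved most without scaling, and shared percentages with how many summits an alternative keeps or how wide it reaches, which follows from its construction; for other moves the cause was not tested, and unknown depth limits all comparisons of numbers. The order of the shares in P7, vitamin C above untreated, held except where only the untreated list was cut to its tallest 10%. Of these summits 34.8% had a P7 summit, against 34.1% of the whole vitamin C list (ratio 0.980, 0.956 to 1.005). In the order untreated in vitamin C, vitamin C in untreated, P7 in untreated, P7 in vitamin C, untreated in P7, vitamin C in P7, the shared percentages were 40.8, 31.0, 13.3, 25.8, 18.0 and 26.6 with the tallest 50% of each list; 35.5, 35.5, 14.1, 23.7, 14.1 and 23.7 with an equal number of the tallest; 38.9, 29.6, 14.9, 26.6, 20.1 and 27.4 within 100 bp; and 62.6, 47.6, 28.8, 43.7, 39.1 and 45.1 within 500 bp. The tallest 50% are 95144 untreated, 125004 vitamin C and 128827 P7 summits. Gene bodies of protein-coding genes alone held 56.1% of untreated, 57.2% of vitamin C and 54.6% of P7 summits, and gene bodies held 65.7%, 68.0% and 65.8% of the tallest 50%. Gene edges held 15.8%, 15.9% and 16.5% within 2 kb, 4.93%, 4.70% and 4.90% within 500 bp, 4.57%, 4.62% and 4.71% for protein-coding genes, and 8.22% of untreated and 9.05% of P7 summits in the tallest 50%. Genes higher and lower under vitamin C numbered 282 and 6 unscaled, 34 higher when scaled outside genes, 8 and 18 with the tallest 50%, and 9 and 24 with an equal number of the tallest. Most of the higher calls in these last 2 alternatives were other genes. The main calls included 2 of the 8 and 12 of the 18, and 1 of the 9 and 9 of the 24. Fewer genes reached the minimum there, 1689 and 1473 in place of 3134. For P7 against untreated cells the calls numbered 444 and 45 unscaled, and 132 lower with an equal number of the tallest, 76 of them among the main calls. Gene-list medians in the outermost 2.5% at either end numbered 6 of 45, against 2.25 by chance, and 17 of 57 with no minimum beyond 1 summit. Of the 60 named gene ratios, 57 kept an interval that excluded 1 on the same side with unscaled counts and 45 with the tallest 50% of each list; 3 and 15 kept the direction with an interval that reached 1.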

Other observations

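All tests of explanations in this part were chosen after the patterns had been seen, except the thinning of the vitamin C list, which was planned. Several gene lists differed in how densely they carried 5hmC at all, compared with genes of the same length. Glutamate and GABA receptor genes lay at percentile 0.78 of such random lists in untreated, 0.18 in vitamin C and 0.98 in P7 cells, and synaptic adhesion and scaffold genes at 0.55, 0.40 and 1.17. Migration and polarity genes lay at 98.6, 98.1 and 98.8, and anterior brain patterning genes at 99.9, 97.7 and 99.3. The 23 Hox genes carried 4 summits in untreated cells and 0 in the other groups, and 20 of them had none in any group; Hoxb3 held 2 of the 4.

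Cell cycle genes, which are short and mostly fell under the minimum for a median, held 26 summits in untreated, 57 in vitamin C and 69 in P7 cells when all 24 members were summed. Their share was 1.67 times as high in vitamin C as in untreated cells (1.03 to 2.76) and 1.96 times as high in P7 cells (1.23 to 3.21). Random genes of the same length also carried more summits in the longer lists, 8.93, 13.1 and 14.5 per 100 kb. Cell cycle genes lay at density percentiles 21.3, 83.2 and 94.7 among them, none in the outermost 2.5%. Over all protein-coding genes the densities were 10.3, 13.8 and 13.6. Genes of this length thus rose more than genes in general, so a scaled ratio of 1 is not their reference level. Summed P7 to untreated ratios had intervals below 1 in 8 lists, which were Purkinje cell (0.757, 0.666 to 0.861), inhibitory interneuron (0.705, 0.559 to 0.889), oligodendrocyte (0.709, 0.506 to 0.993), axon guidance (0.773, 0.724 to 0.826), anterior patterning (0.774, 0.643 to 0.933), progenitor (0.802, 0.645 to 0.997), chromatin remodeling (0.860, 0.763 to 0.969) and migration genes (0.895, 0.818 to 0.979). A ratio of 1 was not the level of genes in general, since the median log2 ratio of all measured genes was -0.13. Set against matched random lists, the medians of chromatin remodeling, interneuron and migration genes lay at percentiles 71.7, 54.8 and 47.7. Of these lists only axon guidance, at 0.03, lay in the outermost 2.5%. Summed housekeeping genes had 16, 34 and 34 summits. Their vitamin C to untreated ratio was 1.62 (0.869 to 3.14) and their P7 to untreated ratio 1.57 (0.843 to 3.04). The vitamin C to untreated ratio of pluripotency genes was 0.829 (0.587 to 1.17) and that of mesoderm and endoderm genes 0.913 (0.617 to 1.36). Across 3234 genes, which are not independent replicates, the log2 ratios of vitamin C and of P7 over untreated cells correlated with r = 0.568, where splits with no difference gave 0.575 (SD 0.0147) because both ratios share the untreated list. The covariance was 0.147 against 0.135 (SD 0.00623) in those splits, a difference of 0.0122.

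More P7 sites lay in the vitamin C list than in the untreated list. List length accounts for part of it but not the whole, since thinning lowered the vitamin C share from 33.1% to 25.2%, still 1.28 times the untreated share of 19.7%. Thinning removes summits of any height, so it does not stand for a shallower list. Shallow untreated summits cannot be told apart from an effect on P7 sites. In the tallest of 5 height classes the vitamin C list shared 47.4% with P7 against 32.9%, a ratio of 1.44. A cut at the same rank keeps a difference in depth between lists, and 32.9% of the tallest untreated summits is near the 34.1% of the whole vitamin C list. Where only the untreated list was cut, the ratio was 1.16 with its tallest 50% and 0.980 with its tallest 10%. That ratio moves with the cut, so it cannot set how much depth explains. Imprecise untreated positions may explain part of it: within 1000 bp the excess over nearby shifts was 23.1 points for vitamin C and 20.6 for untreated summits, a ratio of only 1.12, though still above 1. Read depth, a difference between the library preparations and vitamin C itself stay open, because each condition has 1 list.

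Vitamin C summits were relatively scarce where P7 summits were sparse. Ranking by P7, the list closer to vitamin C, is not the whole cause but may add to it, since the ratio was 0.659 (0.630 to 0.689) in the class of windows with the smallest share of bases inside genes. False untreated summits were tested only in part. In the 3 sparsest classes, untreated summits without a vitamin C partner lay at a P7 summit 5.11 times as often as after nearby shifts (4.76 to 5.48). The shares were 8.86% (727 of 8206) against 1.73%, so these summits were not all placed at random. The test cannot tell how many of the others are false, or whether false summits recur at the same place in both lists. Shallow untreated summits cannot be told apart from an effect on sparse regions: the ratio in the sparsest class was 0.402 with the tallest 50% of each list, but that cut keeps a difference in depth, and the tallest 25% of untreated summits held 0.332% in that class, near the 0.322% of the whole vitamin C list (ratio 0.969, 0.817 to 1.16). A stricter effective cutoff in the vitamin C list and an effect of vitamin C on 5hmC-poor regions stay open.

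Chromosome X held relatively few vitamin C summits. Shallow X summits cannot be told apart from an effect on X: the ratio to untreated cells was 0.333 (0.267 to 0.413) with the tallest 50% of each list, but that cut keeps a difference in depth, and the tallest 50% of untreated summits held 0.295% on X against 0.371% of the whole vitamin C list. The trend of sparse autosomal regions cannot be told apart from an effect on X either. Autosomal windows with the same P7 density as X windows gave a median ratio of 0.635 (0.588 to 0.685) over 1000 random draws. The X interval of 0.514 to 0.611 overlaps that range, but it covers counting error and the range covers the draw of windows. The P7 to untreated ratio on X was 0.954 (0.886 to 1.03), but 0.707 (0.596 to 0.839) with the tallest 50% of each list, and the sex of the cells was not used here.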
